A study of Homo sapiens with 6 samples.

How the data were processed

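Chromatin immunoprecipitation (ChIP) with a BCL6 antibody or an actin antibody, the latter serving as negative control, was read on 6 two-colour custom tiling arrays, 3 per antibody. The cells were Ramos, an established human Burkitt lymphoma B-cell line. Per the labels, Cy5 marked the ChIP DNA and Cy3 the matching input DNA on every array, with no dye swap, so a dye effect common to all arrays cancels in a comparison of antibodies but not in a ratio of ChIP to input. Groups and replicate numbers came from the sample titles. All 6 arrays lay on 1 slide, with the 3 actin arrays in a single column of wells and the 3 BCL6 arrays in another, so position on the slide and antibody cannot be told apart.

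The deposited scanner reports hold a linear intensity per probe and channel, per the file headers. Image software and background treatment are not given in the sources used here, and the mismatch column held 0 throughout. The authors' deposited value table states no scale or centring, but holds uncentred log2 ratios of Cy5 (ChIP) over Cy3 (input), since each value lay within 5e-05 of log2 Cy5 over Cy3 of the same probe. Its column medians were -0.18, -0.20 and -0.30 for actin replicates 1 to 3 and 0.18, 0.18 and 0.08 for BCL6 replicates 1 to 3. Per the labels, the authors took the ratio of Cy5 to Cy3 as enrichment and called a potential hit where more than 5 oligonucleotides exceeded 2.5-fold.

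The array holds 13075 probes in 21 loci. Positions are given as in the files, whose genome build is not given in the sources used here, and they mark the start of a probe. The files name loci by older gene names. Of these, 18 matched a symbol or synonym in an NCBI gene table of assembly GRCh38.p14, used for names only, while the remaining 3 (CD23B, CYCLINA2 and CYCLIND2) were read as FCER2, CCNA2 and CCND2. All 21 loci lay on the chromosome of the gene so named. Exons, introns and transcription start sites could not be assigned without an annotation of the same build.

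Log2 ratios of Cy5 over Cy3 were computed per probe and centred on each array's median, with no background subtraction and no loess or quantile step, since an immunoprecipitated fraction may shift many probes one way. Centring removed a shift of 0.37 (log2) between the mean medians of BCL6 and actin arrays, and every fold below is relative to the array median. A run was a series of at least 6 consecutive probes, at most 500 bp apart, each over 2.5-fold in the mean of the 3 arrays of an antibody. Windows were non-overlapping sets of 6 consecutive probes laid from the start of each locus without regard to the values, giving 2125 windows and leaving 325 probes out. Probes, windows, loci and runs were each compared between antibodies with limma (lmFit and eBayes) on log2 ratios, with Benjamini-Hochberg adjustment over all features of that kind and a threshold of 0.05. Neighbouring probes share DNA fragments and are not independent. Gene lists were tested over the windows of their tiled members with limma's fry, which asks whether a list's windows move, on balance, one way, with adjustment over the 5 lists that had at least 2 tiled members. Numbers of runs per array were compared with an exact two-sided permutation test. The programs were R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 for figures.

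The design, the gene lists and the rule for naming features were fixed before the data were examined. The rule named at most 20 runs in the BCL6 mean and 5 in the actin mean, by mean ratio, the 10 largest positive and 5 largest negative window differences past the threshold with 1 per locus, the tiled members of the lists, and the BCL6 locus. Alternatives were no centring, centring on the Tukey biweight mean, loess, quantile normalization, the authors' value table, leaving out the dimmest 10% of probes, the ChIP channel alone, the replicate number as a block, array weights, a variance trend, other thresholds, window sizes and run rules, and leaving out each array in turn. Leaving single loci out of the lists was chosen after seeing the data.

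The steps were tested on simulated data. Noise was drawn independently for each probe with its measured spread. Neighbouring probes in the data are not independent, so the rates below may be too favourable. With 200 of the 2125 windows shifted by known amounts, the window comparison recovered 76% of the windows shifted by 0.5 (log2). It recovered 100% of those shifted by 1, by 2 or by -1, and 6.47% of its calls were false. Runs were planted on a flat background, where unshifted probes differed only by noise, whereas real ratios vary from probe to probe. All 20 planted runs of 8 probes shifted by 2.5 (log2), well over the run threshold, were found there. Planted runs of 6 probes, 100 per shift, were found in 66%, 96% and 100% of cases at shifts of 1.6, 2 and 2.5 (log2), so runs as low and short as the weakest called here are partly missed. Recovery in the data may be lower, since a single low probe ends a run. Each group has 3 arrays, which limits the precision, and nothing in the labels says that the replicates came from separate cultures. Distance to transcription start sites, the BCL6 motif and probe GC content were not analysed here. Values of 1 tiled locus are not reported here on their own.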

Results

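BCL6, a zinc-finger transcriptional repressor of germinal-centre B cells, was mapped by ChIP in Ramos cells, a human Burkitt lymphoma line, and set against ChIP with an actin antibody as the negative control. The 6 arrays, 3 per antibody, tiled 21 loci with 13075 probes at a median spacing of 27 bp, in tiles of 3008 to 55748 bp. Median intensity of the input channel ranged from 581 to 698 over the arrays, and that of the ChIP channel from 502 to 547 in actin and from 657 to 728 in BCL6 arrays. Centring on the array median removed the resulting shift of 0.37 (log2). Across probes, which are not independent replicates, Pearson's r was 0.717 to 0.765 between BCL6 arrays, 0.615 to 0.686 between actin arrays and 0.218 to 0.245 between antibodies; Spearman's rho was 0.588 to 0.633, 0.571 to 0.631 and 0.260 to 0.302. The labels do not say whether replicates were separate cultures, so all p-values measure the spread between arrays, which may be technical.

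The first comparison asked where BCL6 ChIP DNA exceeded input by the rule of more than 5 oligonucleotides over 2.5-fold. The BCL6 mean held 22 such runs in 11 loci, of which 19 overlapped no run in the actin mean. The highest of these 19 lay in the BCL6 gene itself, on chromosome 3. From 188943985 to 188944164 the ratio was 5.91-fold over the array median in BCL6 ChIP (log2 2.56 ± 0.15, SD, n = 3) and 0.394-fold in actin ChIP (log2 -1.34 ± 0.22, SD, n = 3). The next run, from 188944218 to 188945368, was the longest at 1150 bp and 36 probes, with 5.70-fold in BCL6 ChIP (log2 2.51 ± 0.14) and 0.438-fold in actin ChIP (log2 -1.19 ± 0.03).

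A pair of further BCL6-locus runs flanked these, from 188945747 to 188946161 with 4.65-fold against 0.491-fold, and from 188940863 to 188941549 with 4.51-fold against 0.576-fold. A run at 188925991 to 188926180 reached 4.17-fold in BCL6 ChIP but also 2.43-fold in actin ChIP, the smallest difference among the 19 (0.78 log2). At the strongest of the 19 runs actin ChIP lay below the array median, so the difference between antibodies exceeded the enrichment over input. The highest of all BCL6 runs, starting at 188929538 in the BCL6 locus, was not among them. It was 6.24-fold in BCL6 ChIP and 5.35-fold in actin ChIP.

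**Figure D1:**
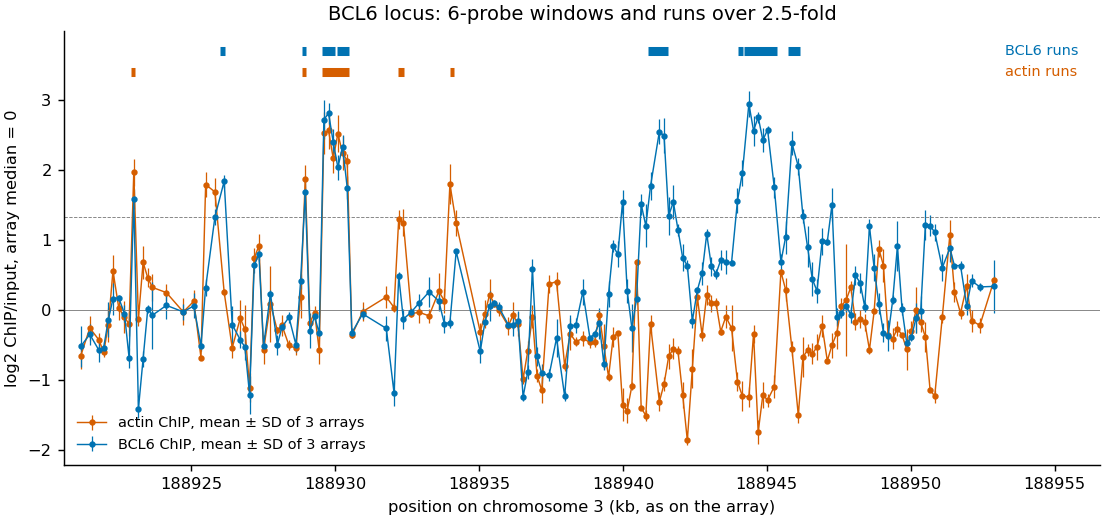
Log2 ChIP/input ratio (array median = 0) of 6-probe windows along the BCL6 locus against position on chromosome 3 in kb, as mean ± SD of 3 arrays for BCL6 ChIP (blue) and actin ChIP (orange). Bars at the top mark the 8 BCL6 and 5 actin runs over 2.5-fold (dashed line); the paired bars left of centre mark where both antibodies are high, and the group of BCL6 bars right of centre has no actin bar.

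Outside its own gene, BCL6 ChIP gave 14 runs in 10 loci. At MS4A1, which encodes the B-cell surface protein CD20, a run on chromosome 11 from 59979644 to 59979914 was 4.71-fold in BCL6 ChIP (log2 2.24 ± 0.20, n = 3) and 0.766-fold in actin ChIP, and a second from 59981627 to 59981789 was 3.67-fold against 1.03-fold. The run at 59979644 was the highest outside the BCL6 locus, although MS4A1 was listed in advance as not expected to be a target. FCER2, the low-affinity IgE receptor CD23, held runs on chromosome 19 from 7676571 to 7676814 (4.51-fold against 0.670-fold) and from 7672621 to 7672837 (4.40-fold against 0.420-fold), the latter called in 1 of the 3 BCL6 arrays when these were taken singly. Among activation antigens, CD80, a costimulatory ligand, reached 4.31-fold on chromosome 3 from 120745886 to 120746102, and CD69 reached 3.97-fold and 3.82-fold on chromosome 12 from 9808642 to 9808993 and from 9809047 to 9809237. The chemokine gene CCL3 had 4.30-fold on chromosome 17 from 31441652 to 31441895. The checkpoint kinase gene CHEK1 had 4.25-fold on chromosome 11 from 125001091 to 125001253, where actin ChIP was at 0.278-fold. PRDM1, which drives plasma cell differentiation, held runs on chromosome 6 from 106652319 to 106652589 (3.90-fold) and from 106652022 to 106652265 (3.75-fold). CDKN1A, the cyclin-dependent kinase inhibitor p21, had 3.51-fold on chromosome 6 from 36761904 to 36762039, and CCND2 and CDKN2A held the 2 lowest runs, at 3.45-fold and 3.03-fold. The CDKN1A and CCND2 runs were called in 2 of the 3 BCL6 arrays taken singly and the CDKN2A run in 1. At these runs of CD80, CD69, CCL3, PRDM1, CDKN1A, CCND2 and CDKN2A, actin ChIP lay between 0.600-fold and 0.976-fold.

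All 19 runs were higher in BCL6 than in actin ChIP by limma, with differences of 0.78 to 3.93 (log2) and adjusted p of at most 8.59e-07. They were chosen by their BCL6 values and by lacking an actin run, so the direction was largely set by the choice. Every run had the same standard error of 0.15, so these p-values rest on a variance pooled over runs, not on each run's own spread. After loess 16 of the 19 passed and 3 did not. These were the BCL6-locus run at 188925991 (from 0.78 to 0.17, limma adjusted p = 0.282), the MS4A1 run at 59981627 (from 1.83 to 0.18, adjusted p = 0.197) and the CDKN2A run, which turned from 1.90 to -0.20 (adjusted p = 0.171). Of the 22 runs, 18 were called in each of the 3 BCL6 arrays. Without BCL6 replicate 3 the loci holding a BCL6-only run numbered 8, with CCND2, CDKN1A and CDKN2A lost. Loess within arrays gave 3 BCL6 runs, at CD69, CD80 and PRDM1.

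The negative control had runs of its own: the actin mean held 14 in 6 loci, of which 12 overlapped no BCL6 run and 7 were called in each of the 3 actin arrays. The highest actin ratio lay in the BCL6 locus from 188933999 to 188934134, at 5.93-fold (log2 2.57 ± 0.25, n = 3) against 2.59-fold in BCL6 ChIP. At CCND2, the cyclin D2 gene on chromosome 12, actin ChIP reached 5.49-fold from 4252797 to 4252932 and 5.25-fold from 4287095 to 4287419, where BCL6 ChIP was at 0.917-fold and 0.762-fold. The BCL6-locus run from 188922903 to 188923038 had 5.20-fold in actin and 3.68-fold in BCL6 ChIP.

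Both antibodies were high together in part of the BCL6 locus. From 188928836 to 188928998 the ratio was 4.91-fold in BCL6 and 5.01-fold in actin ChIP, a difference of -0.03 (log2, standard error 0.15, limma adjusted p = 0.867), but -1.24 after loess (adjusted p = 6.25e-05) and 0.34 without centring (adjusted p = 0.0141). The stretch from 188929538 to 188930483 was 1 run in actin ChIP (5.13-fold, against 5.07-fold in BCL6 ChIP) and was split by 1 probe into 2 runs in BCL6 ChIP, at 6.24-fold and 4.24-fold. With median centring and all arrays none of these 3 shared BCL6 runs passed the threshold, but the call and its direction turned with the scaling, and after loess all 3 were lower in BCL6 ChIP. The one starting at 188929538 differed by 0.22 and passed as higher without actin replicate 3 (0.35, limma adjusted p = 0.0243), after quantile normalization (0.20, adjusted p = 0.03) and without centring (0.60, adjusted p = 2.63e-05). After loess it was lower (-0.97, adjusted p = 0.000721), and leaving out 1 array gave 0.09 to 0.35. The one starting at 188930051 differed by -0.20 (adjusted p = 0.196), by -1.15 after loess (adjusted p = 0.000309) and by -0.36 after quantile normalization (adjusted p = 0.000285), and leaving out 1 array gave -0.30 to -0.11.

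**Figure D2:**
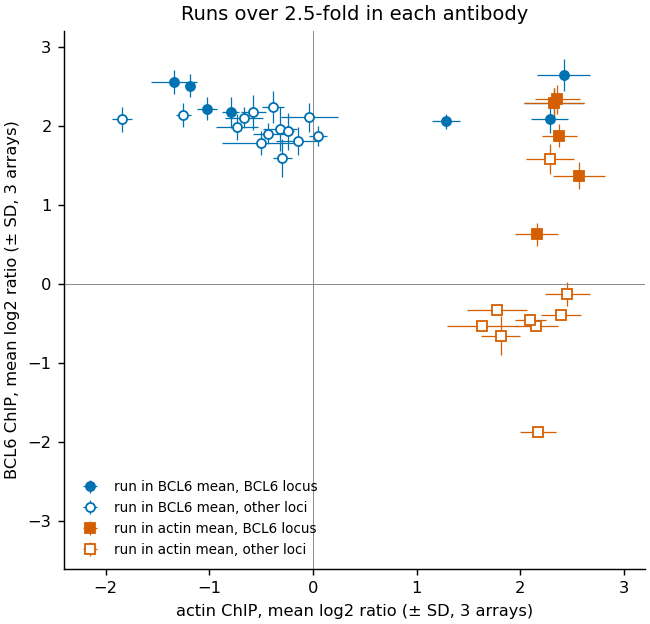
Mean log2 ChIP/input ratio (array median = 0) of each run over 2.5-fold in BCL6 ChIP (vertical axis) and actin ChIP (horizontal axis), with SD over 3 arrays; circles are the 22 runs called in the BCL6 mean, squares the 14 called in the actin mean, filled in the BCL6 locus. Runs that are high with both antibodies, at the upper right, are in the BCL6 locus except 1 at HPRT1.

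Single arrays gave 18, 19 and 28 runs in BCL6 ChIP and 8, 13 and 17 in actin ChIP, means of 21.7 ± 5.51 and 12.7 ± 4.51 (SD, n = 3 each). The exact two-sided permutation p was 0.1, the smallest that 3 against 3 arrays allow, and after loess the difference of means turned from 9 to -7. Runs called in a single BCL6 array were then read in the 2 BCL6 arrays that had no part in the call. Runs of replicates 1, 2 and 3 gave 4.82-fold, 4.36-fold and 3.59-fold there, and 0.950-fold, 0.860-fold and 0.826-fold in actin ChIP. Of these, 18 of 18, 19 of 19 and 27 of 28 were over 2.5-fold in both other BCL6 arrays, and 15, 17 and 25 lay above every actin array in both.

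The second comparison tested BCL6 against actin ChIP in windows of 6 probes set without regard to the values. The largest difference again lay in the BCL6 locus, at 188944633 to 188944768, with log2 ratios of 2.75 ± 0.08 in BCL6 and -1.74 ± 0.17 in actin ChIP (SD, n = 3), a difference of 4.50 ± 0.12 (standard error; adjusted p = 4.73e-13). CHEK1 followed with 3.99 ± 0.12 at 125001091 to 125001226 (adjusted p = 7.9e-13), then CD69 with 3.33 at 9808723 to 9808858 and FCER2 with 3.30 at 7672675 to 7672810. The largest windows of CCL3 (31441544 to 31441679), MS4A1 (59979725 to 59979860), CDKN2A (chromosome 9, 21985216 to 21985351), CCND2 (4252068 to 4252203), PRDM1 (106652346 to 106652481) and CDKN1A (36756106 to 36756242) differed by 2.89, 2.81, 2.75, 2.71, 2.68 and 2.47. Lower in BCL6 ChIP were windows at FCER2 (7663899 to 7664034, by -3.80, with actin ChIP at 3.87-fold), CCND2 (4287230 to 4287365, -2.96), CDKN2A (21960446 to 21960581, -2.68), PRDM1 (106634713 to 106634848, -2.50) and CHEK1 (125001577 to 125001712, -2.13). After loess the 10 higher windows still passed but differed by 0.57 to 1.69, which is 1.66 to 5.80 times less, and the 5 lower ones by -3.56 to -2.24.

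Of 2125 windows, 263 were higher and 137 lower in BCL6 ChIP by limma at an adjusted p of 0.05, and 125 and 44 of them differed by at least 1 (log2). The BCL6 locus held 61 of the 263, or 23.2%, with 7.14% of the probes. It also held 21 of the 137 lower windows. Of the 455 probes over 2.5-fold in the BCL6 mean it held 191, and of the 242 in the actin mean 86. Every locus had at least 1 higher window and 19 of 21 had at least 1 lower one. Among the higher windows, 49 were over 2.5-fold in BCL6 ChIP and 41 lay at or under the array median, and among the lower ones 20 were over 2.5-fold in actin ChIP. Of 13075 probes, 881 were higher and 392 lower. The 2 antibodies' arrays did not overlap in 32.6% of windows and 24.3% of probes, where chance gives 10%. These windows split nearly evenly, with 339 higher and 353 lower in BCL6 ChIP. Higher calls made up 65.8% of called windows and 69.2% of called probes, against 94.5% and 86.7% without centring and 49.4% and 48.9% after loess.

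The third comparison took each locus as a whole. The BCL6 locus (chromosome 3, 188921082 to 188954417) was highest, with a mean log2 ratio of 0.44 ± 0.06 in BCL6 and -0.11 ± 0.01 in actin ChIP (SD, n = 3), a difference of 0.55 (95% interval 0.48 to 0.61, adjusted p = 7.54e-07), and 61 of its 155 windows higher against 21 lower. CDKN1A (chromosome 6, 36749625 to 36763489) followed with a difference of 0.31 (0.27 to 0.35, adjusted p = 7.54e-07), with 18 of 60 windows higher and 0 lower. GAPDH (chromosome 12, 6513004 to 6518751), a glycolytic enzyme gene listed in advance as not expected to be a target, also differed by 0.31 (0.26 to 0.36, adjusted p = 2.95e-06), with 12 of 31 windows higher and 3 lower, but by -0.26 after loess. Loess also lowered the differences of the BCL6 locus and CDKN1A, to 0.12 and 0.038 (limma adjusted p = 0.00415 and 0.0465). Both CDKN1A and GAPDH lay below the array median in BCL6 ChIP (-0.18 and -0.39) and further below it in actin ChIP (-0.49 and -0.70).

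FCER2 (0.17), CCL3 (0.15), CD69 (0.12), MS4A1 (0.11) and PDCD2 (0.10) were also higher, which made 8 loci higher, and CCL2 at 0.13 did not pass (adjusted p = 0.0541). It passed, however, without actin replicate 1 (0.19, adjusted p = 0.000416), with the Tukey biweight mean, without dim probes and with array weights (adjusted p = 0.04, 0.0448 and 0.016). Leaving out 1 array moved it between 0.07 and 0.19. CD44 (-0.10), IL18 (-0.09), HPRT1 (-0.06), NFKB1 (-0.06) and ATR (-0.05) were lower, each by less than 0.1, and all 5 turned positive without centring. ATR, NFKB1 and HPRT1 did not pass when the dimmest 10% of probes were left out (limma adjusted p = 0.702, 0.312 and 0.0621), nor did ATR without BCL6 replicate 2 (adjusted p = 0.0504). ATR and HPRT1 also did not pass after loess (adjusted p = 0.112 and 0.228) or in the ChIP channel alone (adjusted p = 0.412 and 0.125). Median window differences of CCL3, CD69, MS4A1 and PDCD2 were below 0 (-0.10, -0.05, -0.06 and -0.03), and those of CDKN1A and FCER2 were 0.03 and 0.02, so these 6 locus means rested on a minority of windows. The BCL6 locus had a median of 0.14 against a mean of 0.55, so its mean too was raised by part of its windows, and GAPDH had 0.21 against 0.31. Among loci with a BCL6 run, CDKN2A (0.02), CHEK1 (0.01), CCND2 (-0.01), PRDM1 (-0.03) and CD80 (-0.05) did not pass the test as a whole. CD80, however, passed as lower without actin replicate 2 (-0.07, limma adjusted p = 0.00686) and after quantile normalization (-0.09, adjusted p = 0.00403), and PRDM1 and CCND2 did so after loess and after quantile normalization. Higher loci made up 61.5% of the 13 called, against 100% without centring, 38.5% after loess, where FCER2 fell to -0.26 and CCL3 to -0.01, and 47.1% after quantile normalization.

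**Figure D3:**
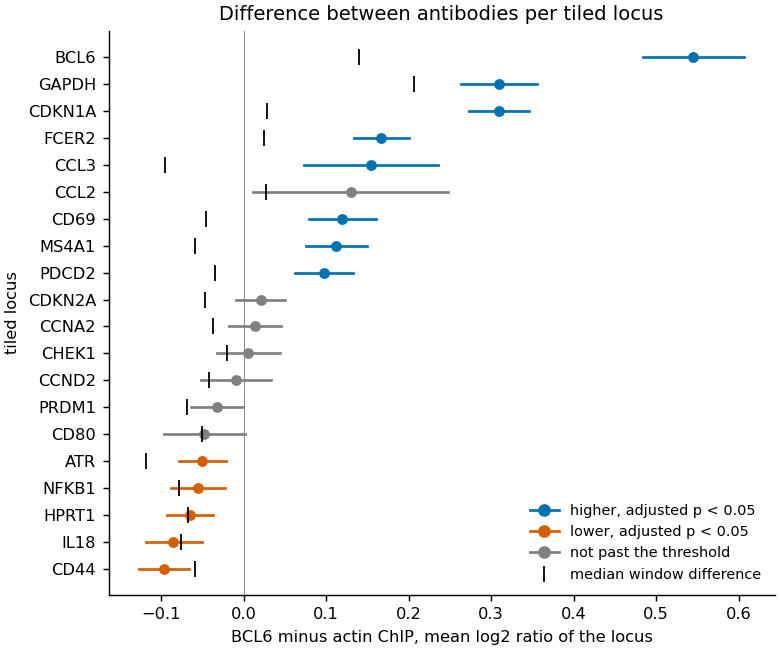
Difference in mean log2 ChIP/input ratio between BCL6 and actin ChIP for 20 of the 21 tiled loci (points, with 95% intervals from 3 arrays per antibody), coloured by direction where the adjusted p passed 0.05; black ticks are the median over the locus's windows. By its mean the BCL6 locus stands apart at 0.55 (0.12 after loess). GAPDH (0.31, but -0.26 after loess) lies level with CDKN1A (0.31, but 0.038 after loess), and HPRT1 is slightly lower (-0.06, but 0.31 without centring). By median window difference GAPDH (0.21) lies above the BCL6 locus (0.14).

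Lists fixed in advance grouped the tiled genes. The test of a list did not set it against the other windows. Higher windows made up 12.4% of all windows, 10.4% of those in the DNA damage list and 23.1% in the cell cycle list. The shares were 6.09% in the B-cell activation list, 7.3% in the chemokine list and 12.4% in the list of genes not expected to be targets. In the list of DNA damage and checkpoint genes, 4 of 9 genes were tiled, among them ATR, CHEK1 and CDKN1A, and 31 of their 298 windows were higher and 12 lower (30 and 11 adjusted over the list alone). The list was higher in BCL6 ChIP (fry adjusted p = 0.0187), with a mean window difference of 0.05 and a median of -0.03. CDKN1A carried 18 of the 31 windows, ATR 7 and CHEK1 3, and without CDKN1A the direction turned (mean -0.02, adjusted p = 0.0663). The call was also lost without BCL6 replicate 1 or replicate 3 (adjusted p = 0.0602 and 0.0606) and with the replicate number as a block (fry adjusted p = 0.104). After loess the list was lower (adjusted p = 0.0454).

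Of the 8 genes of the cell cycle and survival list, CCND2, BCL6 and PDCD2 were tiled, and 103 of 446 windows were higher and 46 lower (106 and 56 adjusted over the list alone; fry adjusted p = 0.000289, higher; mean 0.20, median -0.01). Without the BCL6 locus the adjusted p was 0.842, and after loess it was 0.623 with the opposite direction. In the B-cell activation and plasma cell list, PRDM1, CD69, CD80, CD44 and NFKB1 were tiled out of 12 genes; 40 of 657 windows were higher and 38 lower (35 and 30 adjusted over the list alone), and the test of a shift one way did not pass (fry adjusted p = 0.082; mean -0.03, median -0.06), though the list passed as lower without actin replicate 2 (adjusted p = 0.0417) and after loess (adjusted p = 0.0496) and as higher without centring (adjusted p = 0.00225). In the chemokine list, CCL2, CCL3 and IL18 were tiled out of 7 genes; 10 of 137 windows were higher and 9 lower (9 and 8 adjusted over the list alone; fry adjusted p = 0.687; mean 0.00, median -0.07, direction of the test lower). The list passed as lower after loess (adjusted p = 0.0496) and as higher without centring (adjusted p = 0.0022).

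The list of genes not expected to be BCL6 targets had GAPDH, HPRT1 and MS4A1 tiled out of 7, with 29 of 233 windows higher and 11 lower, the same counts adjusted over the list alone, and was higher in BCL6 ChIP (fry adjusted p = 0.0125; mean 0.04, median -0.05), but lower after loess (adjusted p = 0.0222). GAPDH held 12 of the 29 higher windows, MS4A1 15 and HPRT1 2. Without GAPDH the adjusted p was 0.783 and without MS4A1 0.082. Windows changed in either direction in all 5 lists (fry mixed adjusted p of 1.1e-05 to 1.58e-05). Over all loci 400 of the 2125 windows were called, so this does not set the lists apart. The list of corepressor genes had 0 tiled members.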

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

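The leave-one-locus-out values of the gene lists were chosen after seeing the data, and all other alternatives before. The 15 named windows kept their direction and their side of the threshold in all 225 values recomputed under other settings, but loess reduced the 10 higher ones, of 2.47 to 4.50, to 0.57 to 1.69. Such stability was likely, since they were chosen for the largest differences, and the authors' value table, among the settings, holds the same data. Differences of named runs kept both in 354 values, with 11 reversed, 7 newly past the threshold and 3 no longer past it. For named loci the numbers were 251, 17, 12 and 8. Centring set the split of calls because it removes a shift of 0.37 (log2): without it 1064 windows were higher and 62 lower, 1612 probes higher and 247 lower, 21 loci higher and 0 lower, and 8 actin runs were called. Locus differences then turned to 0.32 for ATR, 0.34 for PRDM1, 0.32 for CD80, 0.28 for CD44, 0.32 for NFKB1, 0.36 for CCND2, 0.29 for IL18 and 0.31 for HPRT1, those of the BCL6-locus runs at 188928836 and 188930051 to 0.34 and 0.17, and that of the actin run at 188929538 to 0.35. The B-cell activation and chemokine lists became higher (adjusted p = 0.00225 and 0.0022). Loess left 207 windows lower, 558 probes higher, 5 loci higher and 8 lower, 3 BCL6 runs, 3 of them with no actin run, 9 actin runs, and a difference of -7 in runs per array. It turned GAPDH to -0.26, FCER2 to -0.26, CCL3 to -0.014 and the BCL6 run at 188929538 to -0.97. The BCL6 runs at 188928836 and 188930051 moved to -1.24 and -1.15, and the CDKN2A run, the lowest and not among the named ones, turned to -0.20. The lists of DNA damage genes and of genes not expected to be targets turned from higher to lower (fry adjusted p = 0.0454 and 0.0222). Those of B-cell activation and chemokines, lower in direction before, now passed (fry adjusted p = 0.0496 each). The cell cycle list no longer passed (fry adjusted p = 0.623), with its direction turned. Loess removes any trend of the ratio with brightness, taken over both channels. Of the brightest 5% of probes 51.5% were over 2.5-fold in BCL6 ChIP, but the ChIP signal enters both measures, so that share is partly built in. Whether the trend is enrichment or a bias was not tested.

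Other settings moved fewer results, and the cause was not tested. Lower loci numbered 9 after quantile normalization, 2 without dim probes and 3 in the ChIP channel alone, and PRDM1 and CCND2 passed as lower after loess and after quantile normalization, and CD80 after quantile normalization (-0.09) and without actin replicate 2 (-0.07). CHEK1 turned to -0.033 after quantile normalization and to -0.0017 with array weights, and in the ChIP channel alone PRDM1 turned to 0.0033, CCND2 to 0.030 and the run at 188928836 to 0.084. Tested over probes, the chemokine list again did not pass (fry adjusted p = 0.926), and only its direction turned to higher. By construction, stricter or looser rules changed counts: a difference of at least 1 left 125 windows higher and 44 lower and 0 loci higher and 0 lower, an adjusted p of 0.01 left 247 probes lower, and windows of 10 probes gave 174 higher. BCL6 runs numbered 35 at 2-fold and 45 at 4 probes (32 and 37 with no actin run) and 35 in the ratio of BCL6 to actin ChIP, and actin runs 7 at 3-fold and 5 at 8 probes. Without CDKN1A the DNA damage list was lower (adjusted p = 0.0663), without BCL6 the cell cycle list had 0.842, and the list not expected to be targets had 0.783 (lower) without GAPDH and 0.082 without MS4A1. Leaving out each array in turn gave differences of -0.0087 to 0.020 for CHEK1, -0.025 to 0.0013 for CCND2, -0.13 to 0.092 for the actin run and 0.09 to 0.35 for the BCL6 run at 188929538 and -0.19 to 0.090 for the run at 188928836, and adjusted p of 0.0348 to 0.0606 for DNA damage, 0.0417 to 0.243 for B-cell activation and 0.386 to 0.825 for chemokines. Deviations of arrays with the same replicate number correlated at 0.02, -0.0042 and 0.0065, and not every array correlated best with its own number, so no spread shared by number was seen. The numbers do match slide position, as replicates 1, 2 and 3 of both antibodies lay in well rows A, B and C. With the replicate block 265 windows were higher and 143 lower, 792 probes higher and 324 lower, 8 loci higher and 5 lower, and the DNA damage list had an adjusted p of 0.104. The block with GC correction, the distances to transcription start sites and the motif counts were not run, for lack of probe sequences and of an annotation of the same build. Signal over background could not be gauged, since the reports held no background values.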

Other observations

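The tests of partial BCL6 gene DNA and of probe sequence, the latter split by locus, were chosen after the runs were seen, and that of input brightness after the loess value of GAPDH was known. The split of the 6 arrays by antibody gave 1273 called probes, 400 called windows and 13 called loci, and the highest of the other splits gave 0, 0 and 0. With 10 splits, of which 1 gave as many in each case, no share under 0.05 is possible.

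High ratios with both antibodies were concentrated in the BCL6 locus. Of 70 probes over 2.5-fold in both means, where independent probes would give 8.42 over all loci and 17.6 within the BCL6 locus alone, which has many high probes with each antibody, the BCL6 locus held 63, HPRT1 5 and MS4A1 2. The HPRT1 probes lay in an actin run on chromosome X from 133319999 to 133320161, at 4.87-fold in actin and 3.00-fold in BCL6 ChIP, singled out after its values were seen.

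Low input signal is argued against for the shared BCL6-locus runs, since their centred log2 Cy3 had a median of 1.98 over all arrays, well above the array median rather than below it. A candidate explanation is DNA in both ChIP samples that holds only parts of the BCL6 gene, such as an expression construct or amplified product. The ratio fell to a median of -0.28 (log2, the higher of both antibodies) at probes 3 to 8 outside their ends, but BCL6 runs that no actin run overlapped also fell, to 0.16, so steep sides do not single out the shared runs, and the HPRT1 run is not accounted for. Whether the runs coincide with exons stays open, since exon positions in the build of the array were not used here, and sequence-dependent hybridisation was not tested for these runs.

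The 12 actin runs that no BCL6 run overlapped had a median span of 162 bp, against 216 bp for the 19 BCL6 runs that no actin run overlapped. A lower input signal on the actin arrays is argued against by a median actin minus BCL6 difference of 0.38 in centred log2 Cy3 (-0.436 to 0.958). At BCL6 runs that no actin run overlapped this difference was mostly negative, from -0.979 (CD69 run at 9809047) to 0.5 (CHEK1 run). The input channel thus tended to be higher with the antibody that had the run, and why was not tested. The 9 outside the BCL6 locus (every actin run there) had a median log2 ratio of -0.46 in BCL6 ChIP. Of these, 8 lay below the array median in BCL6 ChIP, which argues against probe sequence alone for those 8. The HPRT1 run was at 1.58, so probe sequence stays open for it. For the 3 in the BCL6 locus the BCL6 median was 1.37 (0.63 to 1.88), so probe sequence stays open there. Few fragments amplified before labelling, a step not given in the sources used here, stay open too: the actin ratio outside these runs had a median of -0.020, but BCL6 runs that no actin run overlapped had 0.16 (-0.90 to 1.45), which does not part the 2 kinds. DNA brought down by the actin antibody was not tested and may also account for them.

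At locus level GAPDH, not expected to be a target, differed between antibodies as much as CDKN1A. Its mean log2 ratio in BCL6 ChIP was the lowest of the 21 loci (-0.39, against -0.70 in actin ChIP). Under no run setting did the BCL6 mean hold a BCL6-only run at GAPDH, but the ratio of BCL6 to actin ChIP held runs there. Of the GAPDH probes, 2.14% were over 2.5-fold in BCL6 ChIP and 1.6% in actin ChIP. After loess its difference was -83.4% of the value before, and probes of other loci matched on input brightness, without the BCL6 locus, gave 97.0% of it in the mean (0.30 against 0.31) but a lower median (0.098 against 0.19), so a trend of the ratio with brightness may account for part of the GAPDH value. The same matching gave 40.4% of the CDKN1A difference and 141% of the FCER2 difference. It takes the input channel as free of the ChIP, which the input values at the runs leave open. Of the brightest 5% of probes, by the mean of both channels in BCL6 arrays, 51.5% were over 2.5-fold in BCL6 ChIP against 0.95% of the others. That brightness includes the ChIP signal, unlike the input brightness used for matching, so the contrast is partly built in. Enrichment of bright probes was not separated from a bias with brightness. Whether a few strong windows carry GAPDH was not settled, as its median window difference was 66.6% of the locus mean difference, and BCL6 binding at GAPDH remains open.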
